A study of Mus musculus with 12 samples.

How the data were processed

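RNA from 12 samples of primary colonic myofibroblasts was sequenced, 6 from TNFR1 knockout and 6 from heterozygous control mice on a C57BL/6 background, 5 days after seeding in Matrigel, per the labels. Messenger RNA was selected with oligo-dT beads and made into strand-specific libraries by the dUTP method, per the labels' protocols. The deposited table holds expected counts per gene, estimated reads that need not be whole, for 24411 gene symbols and 12 libraries. RSEM 1.2.15 and Bowtie2 2.1.0 are named in the submitters' processing notes. Those notes also name a human genome build, while the row names are mouse gene symbols, so the build behind the counts is uncertain and no coordinates are given. The annotation release and the strand setting of the counting are not given in the sources used here. In each library 2.67% to 3.48% of the values had decimals, and all values were rounded to whole numbers before testing. Near-identical gene copies can share reads in such counts, and overlapping genes on opposite strands are uncertain where the strand setting is unknown.

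Groups and replicate numbers were taken from the sample titles, and all 12 columns matched 1 title each. Total counts per library were 6543013 to 9937008 for knockout and 11890729 to 16458689 for control libraries. The ribosomal RNA precursor gene Rn45s took 1.63% to 2.10% of the counts in knockout 1 to 4, 7.01% (95% Wilson interval 6.99% to 7.03%) in knockout 5, 8.25% (8.23% to 8.26%) in knockout 6, 0.871% to 1.19% in control 1 to 5 and 0.351% (0.348% to 0.353%) in control 6. These intervals cover counting error only.

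Pairs of libraries were compared by Spearman correlation of log2 CPM over genes with a total of at least 120 counts, and by a chi-square of their counts over genes with at least 20. Chi-square per degree of freedom was 1.38 to 9.83 within the 4 sets and 104.8 to 178.8 between sets of 1 genotype, so no pair was within counting noise over all genes. Library preparation of one culture adds to counting noise as well, so this does not show that the libraries are separate samples, and they were kept apart because the design had been fixed beforehand. The median gene was closer to counting noise, with a chi-square 1.10 to 3.93 times its expected median within sets (1.10 for control 1 and 4) and 21.5 to 30.9 times between sets of 1 genotype. The coefficient of variation from the edgeR common dispersion, fitted to all genes together, was 3.42% to 7.92% within sets. It was 39.8% between the knockout sets and 31.7% between the control sets.

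The comparison was knockout against control, with genotype as the only term, tested over all 12 libraries by the edgeR 4.0.16 quasi-likelihood test in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 12146, and libraries were scaled by the trimmed mean of M-values. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Log2 differences are knockout minus control, fold changes come from the fitted log2 differences, folds between sets from log2 CPM of the summed counts, and CPM values use the scaled library sizes. The median log2 difference over all tested genes was 0.02.

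Before the data were examined, 19 pathway lists and 12 lists of cell type or sex-linked markers were fixed, together with the design and the alternatives. Of the cell type lists, those with at least 3 tested genes entered the list tests, except the sex-linked list, which was left out. The list tests covered 27 lists. Lists were tested with camera of limma 3.58.1 (preset correlation 0.01, log2 CPM with a prior count of 2, two-sided), with an estimated correlation, and with fry. Genes named in the text were chosen by a rule fixed at the same time. It takes Tnfrsf1a, then the 6 largest rises and 6 largest falls among called genes with a mean log2 CPM of at least 2 whose 6 knockout libraries all lay on one side of the 6 controls. From each pathway list it takes up to 2 called members with the smallest adjusted p, and from each cell type list 1. Symbols of predicted genes (starting with Gm and a digit, or ending in Rik) were passed over. The rule chose 57 genes, 25 higher and 32 lower, of which 3 are not reported here; Tnf, Xist, Ddx3y, Epcam, Cdh1, Etv1, Wt1, Lyz2, Rn45s, H2-K1, C4b and Cfb were named after their values were seen.

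The alternatives were other scalings (DESeq2 size factors, library totals alone), other tests (DESeq2 1.42.0, limma-voom with and without sample quality weights), no filter or a stricter one (CPM of 1 in 6 libraries), a block for the replicate number, each library left out in turn, and a test against a fold of 1.5. After the counts had been seen, fits on 4 summed sets, fits without knockout 5 and 6 with or without control 6, and a fit without Rn45s were added. The set sums hold 4, 2 and 5 libraries and control 6 alone.

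The scripts were tested on simulated counts for knockout against control with 200 changed genes. With 12 independent libraries, 26.9% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 97% of those changed 4-fold were called among 12085 genes, with 5 false calls. With libraries that share the spread of the 4 sets and no changed gene, the test over 12 libraries called 3958 of 12044 genes and the test on 4 sums called 0. With 200 changed genes and that spread, the test on 4 sums recovered 0% of the genes at each fold among 12146. The simulations with sets were single draws, and the set differences of each gene were drawn independently of other genes. Gene neighbours of Tnfrsf1a were taken from the order of genes in RefSeq for the mouse assembly GRCm38.p6, in which 11572 of the 12146 tested symbols (95.3%) had a place.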

Results

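Gene expression was measured by RNA sequencing in primary colonic myofibroblasts, mesenchymal cells grown out of the distal colon of 16-week-old mice. The cells were at passage 6 to 8 and came from mice lacking TNFR1 (6 libraries) and from heterozygous control mice (6 libraries). TNFR1 is a cell surface receptor through which tumor necrosis factor (TNF) activates NF-kB, and its gene is Tnfrsf1a. The comparison asks which transcripts of the colonic mesenchyme, among them those that act on the epithelial stem cell niche, differ when TNFR1 is absent. Total counts per library ran from 6543013 to 9937008 in the knockout group and from 11890729 to 16458689 in the control group.

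The 12 libraries fell into 4 sets of very similar profiles, which were knockout 1 to 4, knockout 5 and 6, control 1 to 5, and control 6 alone. Rank correlations across genes were 0.989 to 0.998 within a set and 0.927 to 0.955 between sets of the same genotype. Control 6 correlated at 0.953 to 0.955 with control 1 to 5 and at 0.969 to 0.976 with knockout 1 to 4. Knockout 1 to 4 likewise correlated at 0.937 to 0.942 with control 1 to 5 but at 0.927 to 0.929 with knockout 5 and 6. Nothing in the sources used here says which libraries came from separate animals or cultures, so p-values over the 12 libraries measure only the spread between these samples, which may be technical. For that reason the lists that passed camera, and the marker lists whose direction differed between sets, are also given as their median log2 difference in the 4 contrasts of a knockout set with a control set.

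**Figure D1:**
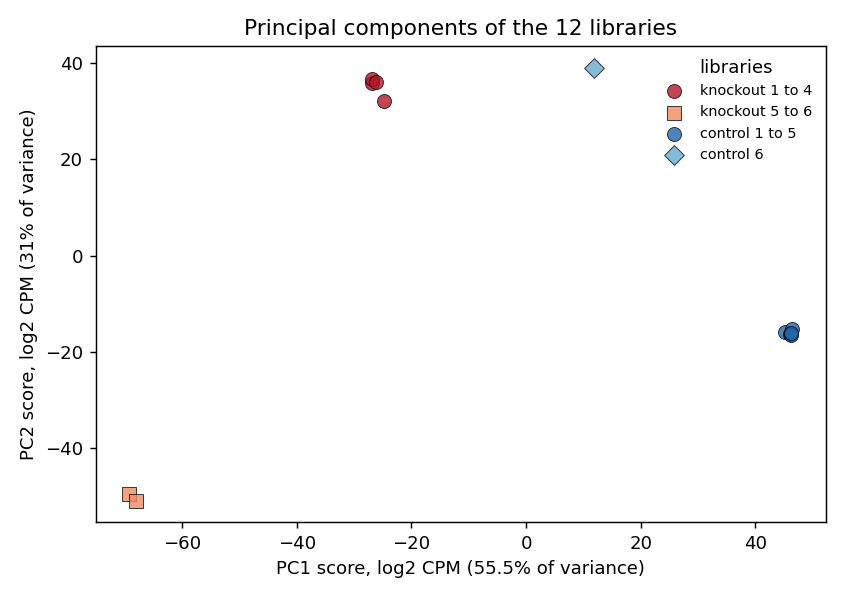
Principal component scores of the 12 libraries (axes in log2 CPM, where CPM is the read count scaled to library size), with 1 point per library and colours for the 4 sets. The first component holds 55.5% and the second 31% of the variance, and control 6 lies at 11.9 on the first, between knockout 1 to 4 (-26.8 to -24.8) and control 1 to 5 (45.1 to 46.4), and at 39.1 on the second, beside knockout 1 to 4 (32.1 to 36.7).

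Tnfrsf1a, the targeted gene, was read in every library and was lower in the knockout group. Its level was 40.6, 44.7, 46.0, 41.8, 46.1 and 45.3 CPM in knockout 1 to 6, and 73.5, 79.5, 78.5, 81.3, 80.9 and 54.9 CPM in control 1 to 6. The knockout mean was 44.1 ± 2.32 CPM (SD, n = 6) against 74.8 ± 10.1 CPM (SD, n = 6), a log2 difference of -0.76 (SE 0.10; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 9.24e-05). Control 6 was above all 6 knockout libraries and below the 5 other controls. Counts per gene do not show which exons the remaining transcript contains.

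In these libraries the knockout cells had lower levels of NF-kB target genes, interferon-stimulated genes, glycolysis and hypoxia genes, and macrophage and leukocyte markers (camera adjusted p = 0.106 to 0.669 with an estimated correlation). They had higher levels of contractile genes, cell cycle genes, BMP pathway genes and several epithelial growth factors (camera adjusted p = 0.557 to 0.683 with an estimated correlation). Contractile genes had a median of -0.20 for knockout 5 and 6 against control 6, and cell cycle genes had medians of only 0.19 and 0.34 in knockout 1 to 4. The epithelial growth factor list had a median of -0.10 for knockout 1 to 4 against control 6. The secreted Wnt inhibitor Sfrp1 and the Wnt-enhancing ligand Rspo3 were 5.89-fold and 5.15-fold lower, and the Notch ligand Jag1 was 7.32-fold higher. Of 12146 genes tested, 5219 passed an adjusted p of 0.05 in the edgeR quasi-likelihood test, 2597 of them higher and 2622 lower in the knockout. These counts were 3055 and 3433 without knockout 5 and 6, and 4319 and 4508 when control 6 was left out as well. That last fit sets knockout 1 to 4 against control 1 to 5, so genotype and set cannot be told apart in it. Its p-values measure only the spread within sets.

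Among the NF-kB target genes, 12 of 22 tested members fell, 3 rose and 7 did not pass the test (12 fell and 4 rose when adjusted over the list alone). Bcl3, a nuclear regulator of NF-kB, fell from 18.6 ± 2.66 to 2.87 ± 0.611 CPM (SD, n = 6 each; log2 difference -2.69, SE 0.16). The leukocyte adhesion molecule Icam1 fell from 26.4 ± 4.10 to 4.66 ± 1.64 CPM (log2 difference -2.51, SE 0.23). Both genes were at least 3.34-fold lower in each knockout set than in each control set, and their edgeR adjusted p-values were 7.31e-07 and 1.07e-05. As a group the list was lower (camera adjusted p = 0.00273; adjusted p = 0.106 with an estimated correlation), with set medians from -0.19 to -0.78. Components of TNF receptor signalling moved both ways, with 6 of 28 higher, 8 lower and 14 not past the test (7 and 10 when adjusted over the list alone; camera adjusted p = 0.444). Chuk, which encodes the kinase IKK-alpha, rose from 45.5 to 86.6 CPM. Tnf itself had at most 6 counts in any library and was not tested.

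**Figure D2:**
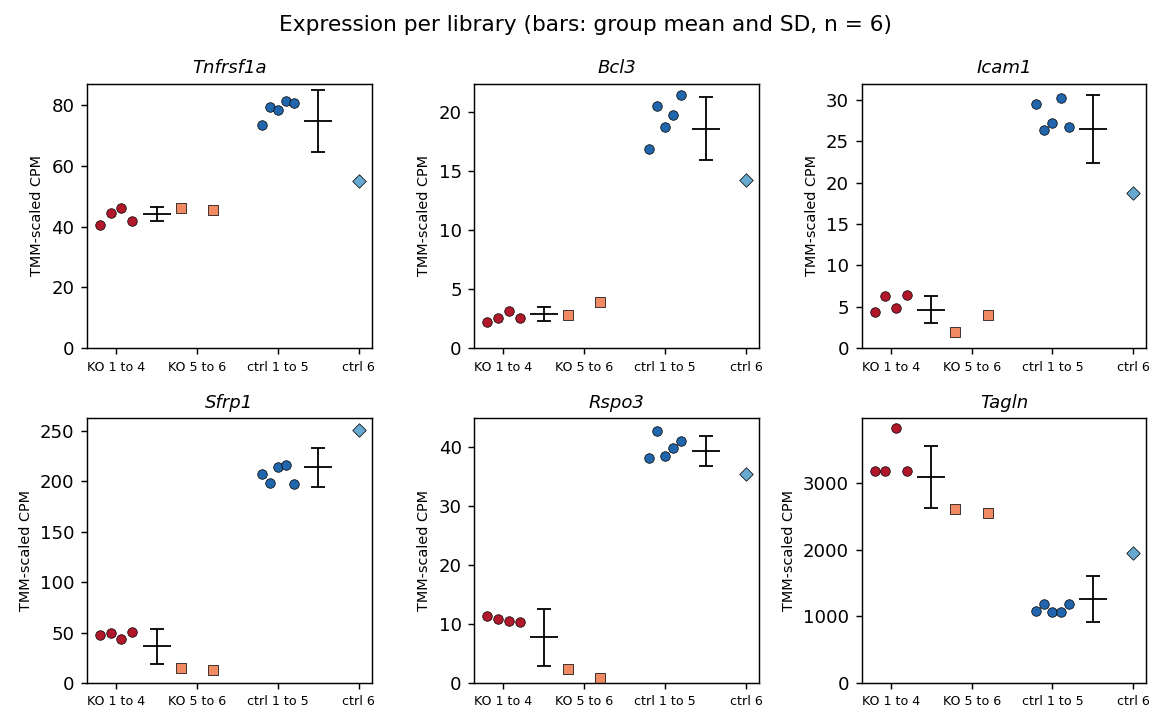
Level of 6 genes in each library (vertical axes in CPM scaled by the trimmed mean of M-values), with points coloured by set, and group mean and SD (n = 6) as bars. Icam1 and Bcl3 were low in all 6 knockout libraries, while Tnfrsf1a in control 6 (54.9 CPM) lay between the knockouts and the other controls.

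Interferon-stimulated genes were lower throughout. Of 24 tested members, 18 fell, none rose and 6 did not pass (18 and 0 when adjusted over the list alone), and all 24 were lower in both knockout sets than in both control sets. The RNA-sensing enzyme Oas1a fell from 16.1 to 1.77 CPM (log2 difference -3.19, SE 0.34) and the immunoproteasome subunit Psmb8 from 24.9 to 4.84 CPM (-2.37, SE 0.32). The set medians ranged from -0.49 for knockout 1 to 4 against control 6 to -3.83 for knockout 5 and 6 against control 1 to 5 (camera adjusted p = 1.18e-06; adjusted p = 0.669 with an estimated correlation). Oas1a belongs to a family of near-identical copies, so its own level is uncertain.

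Macrophage and leukocyte markers were present at low levels and were lower in the knockout, with 11 of 14 falling, none rising and 3 not past the test (12 fell when adjusted over the list alone; camera adjusted p = 1.61e-06; adjusted p = 0.348 with an estimated correlation). The integrin Itgam fell from 2.79 ± 0.369 to 0.594 ± 0.261 CPM (SD, n = 6 each), and set medians ran from -0.84 to -1.78. Glycolysis and hypoxia genes also fell, with 15 of 20 lower, none higher and 5 not past the test (15 when adjusted over the list alone). Ndrg1, a gene induced by hypoxia, fell from 100.2 to 16.3 CPM, and Egln3, an oxygen-sensing hydroxylase, from 42.8 to 14.5 CPM. The smallest fold between a control set and a knockout set was 2.01 for Ndrg1 and 1.13 for Egln3. The set medians of this list were -0.40 to -1.06 (camera adjusted p = 1.61e-06; adjusted p = 0.542 with an estimated correlation).

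Of the Wnt ligands and R-spondins, 6 of 21 members were expressed highly enough to be tested, and 1 rose, 2 fell and 3 did not pass (the same counts when adjusted over the list alone). Wnt5a, a ligand of noncanonical Wnt signalling, rose from 45.9 ± 6.20 to 83.6 ± 6.78 CPM (SD, n = 6 each; log2 difference 0.87, SE 0.10). Rspo3, which strengthens Wnt signals received by crypt stem cells, fell from 39.3 ± 2.55 to 7.70 ± 4.79 CPM (-2.37, SE 0.44). The median of this list was 0.01, its mean -0.22 and its camera direction lower (adjusted p = 0.989). Secreted Wnt antagonists gave 2 lower, 0 higher and 3 not past of 5 (2 lower over the list alone; camera adjusted p = 0.245). Sfrp1 fell from 213.9 to 36.4 CPM (-2.56, SE 0.32) and Frzb from 56.5 to 19.9 CPM (-1.51, SE 0.33). Targets of beta-catenin gave 4 higher, 1 lower and 4 not past of 9 (4 and 1 when adjusted over the list alone; camera adjusted p = 0.289), with Apcdd1 rising from 1.12 to 2.53 CPM and Bambi from 6.14 to 12.2 CPM. Both of these encode membrane proteins that dampen signalling.

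BMP ligands, antagonists and targets gave 12 higher, 1 lower and 5 not past of 18 (12 and 2 when adjusted over the list alone). The BMP target Id4 rose from 2.07 to 13.4 CPM (log2 difference 2.68, SE 0.28) and Id2 from 9.06 to 19.4 CPM (1.09, SE 0.12). Set medians were 0.42 to 1.27 (camera adjusted p = 0.000133; adjusted p = 0.557 with an estimated correlation). In the hedgehog and Notch list, 3 of 14 rose, 3 fell and 8 did not pass (3 and 3 when adjusted over the list alone; camera adjusted p = 0.815). Jag1 rose from 8.62 ± 1.37 to 63.1 ± 42.4 CPM (SD, n = 6 each), at 35.5 CPM in knockout 1 to 4 and 116.7 CPM in knockout 5 and 6, and the Notch target Hes1 rose from 17.3 to 36.6 CPM.

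Contractile and myofibroblast genes gave 15 higher, 0 lower and 2 not past of 17 (15 when adjusted over the list alone; camera adjusted p = 1.18e-06; adjusted p = 0.669 with an estimated correlation). Tagln, an actin-binding protein of smooth muscle, rose from 1257 ± 345.7 to 3092 ± 467.1 CPM (SD, n = 6 each; log2 difference 1.30, SE 0.18), and the intermediate filament gene Vim rose from 2135 to 3791 CPM. Their smallest folds between a knockout set and a control set were 1.33 and 1.21. The set medians reached 1.85 for knockout 1 to 4 against control 1 to 5 but were -0.20 for knockout 5 and 6 against control 6. Smooth muscle markers, all 6 of whose tested members also stand in the contractile list, gave 4 higher, 0 lower and 2 not past (4 over the list alone; camera adjusted p = 0.0186; adjusted p = 0.669 with an estimated correlation). Their set medians ran from 2.42 for knockout 1 to 4 against control 1 to 5 to -0.81 for knockout 5 and 6 against control 6. Lmod1, which nucleates actin in muscle, rose from 48.4 to 194.5 CPM, with a smallest fold between sets of 1.2. The call on the smooth muscle list was lost without knockout 1, 2, 3, 4 or 6 (camera adjusted p = 0.05 to 0.197) and without control 6 (0.081).

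Collagens gave 2 higher, 5 lower and 15 not past of 22 (1 and 5 when adjusted over the list alone; camera adjusted p = 0.243). Col15a1 fell from 150.4 to 26.2 CPM (log2 difference -2.52, SE 0.21) and Col14a1 from 27.2 to 3.59 CPM (-2.90, SE 0.40). For Col14a1 the smallest fold between a control set and a knockout set was only 1.11. Control 6, at 6.1 CPM, was below knockout 5 at 6.64 CPM for this gene. Matrix glycoproteins and crosslinking enzymes gave 1 higher, 5 lower and 22 not past of 28 (1 and 5 over the list alone; camera adjusted p = 0.245), with the small proteoglycan Dcn falling from 621 ± 59.9 to 190.9 ± 27.7 CPM (SD, n = 6 each) and Spp1, osteopontin, from 1773 to 388 CPM. Metalloproteinases and their inhibitors gave 4 higher, 7 lower and 11 not past of 22 (4 and 8 over the list alone; camera adjusted p = 0.22). The stromelysin Mmp3 fell from 74.7 to 6.03 CPM (-3.61, SE 0.29) and Mmp11 from 343 to 70.8 CPM (-2.28, SE 0.29). The TGF-beta list gave 9 higher, 3 lower and 6 not past of 18 (10 and 4 over the list alone; camera adjusted p = 0.22), and both of its named members fell, the matrix protein Tgfbi from 16.4 to 3.95 CPM and the receptor Tgfbr2 from 282 to 146.5 CPM.

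Epithelial growth factors gave 7 higher, 2 lower and 8 not past of 17 (8 and 2 when adjusted over the list alone; camera adjusted p = 0.0186; adjusted p = 0.669 with an estimated correlation). Pdgfa, which encodes a platelet-derived growth factor chain, rose from 22.2 ± 3.05 to 37.4 ± 4.67 CPM (SD, n = 6 each; log2 difference 0.75, SE 0.11; edgeR adjusted p = 0.000218). Set medians ran from -0.10 for knockout 1 to 4 against control 6 to 1.12 against control 1 to 5. The call on this list was lost when any one of knockout 1 to 6 was left out (camera adjusted p = 0.05 to 0.0705), and the adjusted p was 0.291 without knockout 5 and 6 together, 0.00795 when control 6 was left out as well, and 0.137 with no filter on low counts. In the prostaglandin pathway 2 of 13 rose, 2 fell and 9 did not pass (2 and 1 over the list alone; camera adjusted p = 0.733). Ptgs2, the inducible cyclooxygenase, rose from 353 to 1713 CPM, with control 6 at 1080 CPM and control 1 to 5 at 202 to 210 CPM. Ptgir, the prostacyclin receptor, fell from 19.2 to 2.49 CPM.

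Cell cycle genes gave 17 higher, 0 lower and 12 not past of 29 (21 higher when adjusted over the list alone; camera adjusted p = 6.78e-05; adjusted p = 0.683 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose from 32.8 to 140.1 CPM and the mitotic kinesin Kif20a from 27.5 to 42.7 CPM. Set medians were 1.39 and 1.52 for knockout 5 and 6 but 0.19 and 0.34 for knockout 1 to 4, and the camera adjusted p was 0.00784 without knockout 5 and 6 and 0.079 without knockout 5, knockout 6 and control 6. The p53 and senescence list gave 5 higher, 5 lower and 6 not past of 16 (6 and 5 over the list alone; camera adjusted p = 0.989), and its stress-response member Sesn2 fell from 110.7 to 52.8 CPM. For Sesn2 the smallest fold between sets was 1.26. Cholesterol synthesis gave 1 higher, 2 lower and 16 not past of 19 (0 and 1 over the list alone), with a median of 0.16, a mean of 0.18 and a camera direction of lower (adjusted p = 0.989). Its set medians were 0.75 and -0.08 for knockout 1 to 4 but -1.11 and -1.96 for knockout 5 and 6, and without knockout 5 and 6 the list was higher (camera adjusted p = 0.00784; adjusted p = 0.764 with an estimated correlation). Mvd fell from 47.7 to 22.2 CPM.

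**Figure D3:**
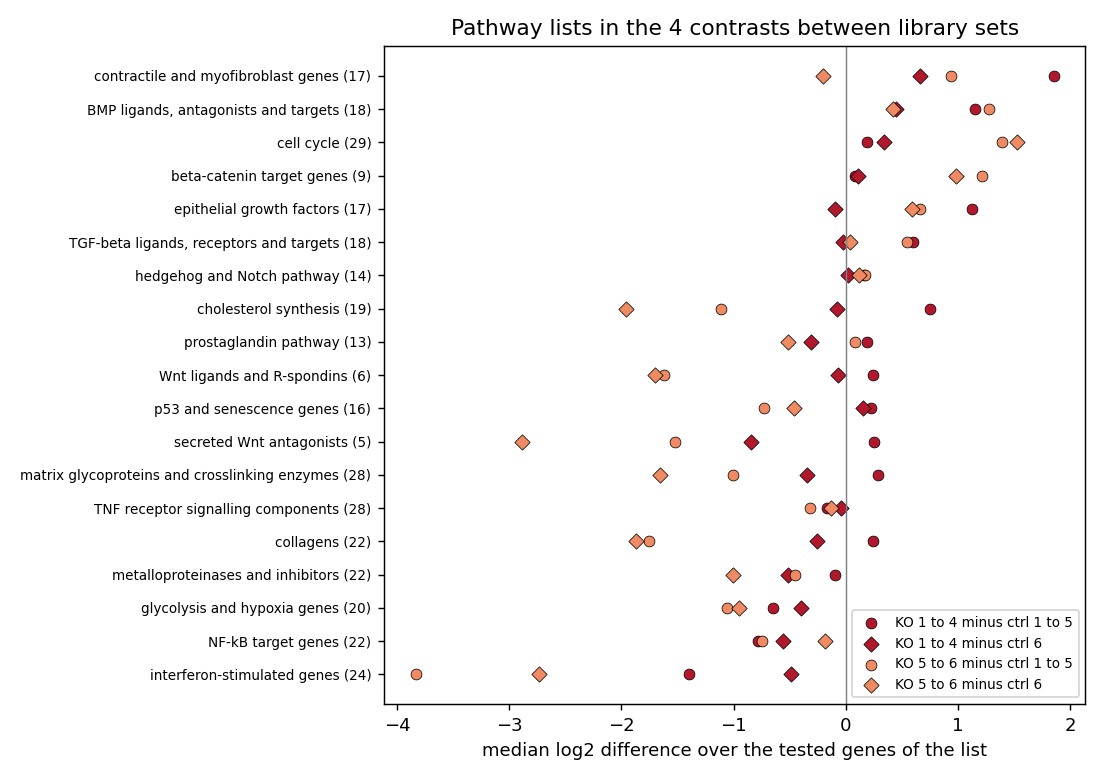
Median log2 difference of each pathway list (horizontal axis; tested members in brackets) in the 4 contrasts of a knockout (KO) set with a control (ctrl) set. Interferon-stimulated genes lie below 0 in all 4 contrasts (-0.49 to -3.83), while contractile genes cross 0 (-0.20 to 1.85).

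Markers of fibroblast subtypes went both ways. The CD34+ CD81+ trophocyte list gave 1 higher, 2 lower and 7 not past of 10 (1 and 2 over the list alone; camera adjusted p = 0.577; set medians 0.55 to -3.97), and its member C3, the central complement component, fell from 43.1 ± 24.1 to 5.00 ± 2.06 CPM (SD, n = 6 each). The PDGFRA-high telocyte list gave 2 higher, 2 lower and 3 not past of 7 (2 and 2 over the list alone; camera adjusted p = 0.577; set medians 0.25 to -0.26), with Wnt5a as its named member. Pericyte markers gave 2 higher, 1 lower and 4 not past of 7 (2 and 1 over the list alone), with a median of 0.32, a mean of -0.09, a camera direction of higher (adjusted p = 0.999) and set medians of 1.04 to -2.28. Ndufa4l2 of that list fell from 43.5 ± 5.02 to 3.03 ± 1.62 CPM, at least 8.83-fold in each contrast of sets.

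Markers of other cell types were mostly near the detection limit. Epithelial markers had 2 of 14 members tested, neither past the test (set medians 1.75 to -0.71), and Epcam and Cdh1 had at most 1 count in any library. Enteric glia and neuron markers gave 1 higher, 4 lower and 1 not past of 6 (1 and 5 over the list alone; camera adjusted p = 0.156), with Uchl1 rising from 10.6 to 24.2 CPM. Endothelial markers gave 0 higher, 1 lower and 2 not past of 3 (1 lower over the list alone; camera adjusted p = 0.815). Tek fell from 4.09 to 1.42 CPM (edgeR adjusted p = 0.0248; 0.0552 without control 3). Adipocyte markers gave 1 higher, 1 lower and 1 not past of 3 (1 and 1 over the list alone), with a median of 0.16, a mean of -0.76, a camera direction of lower (adjusted p = 0.815) and set medians of 0.69 to -1.01; Lpl fell from 151.9 to 18.4 CPM. Of the interstitial cell of Cajal markers, Ano1 rose from 2.13 ± 3.22 to 10.1 ± 6.90 CPM (edgeR adjusted p = 0.0451, but 0.0696 to 0.0856 without any one of knockout 1 to 4 and 0.0812 to 0.0904 without any one of control 1 to 5) and Etv1 did not pass (1 higher and 1 lower of these 2 when adjusted over the list alone). Ano1 was at 14.5 CPM in knockout 1 to 4 but at 1.44 CPM in knockout 5 and 6, below the 8.52 CPM of control 6, and the set medians of its list ran from 1.91 to -2.38. The mesothelial marker Wt1 did not pass the test, with set differences of -1.63 to 2.86. The Y-linked gene Ddx3y had 586 to 1315 counts in all 12 libraries and Xist at most 4, and 3 of the 4 sex-linked genes tested were higher in the knockout, with 1 not past (set medians 1.02 to -0.23).

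Among genes that parted all 6 knockout from all 6 control libraries, large rises were seen in Serpinb2, Rassf6, Prl2c4, Npnt and Cd24a, with log2 differences of 3.23 to 6.74. Serpinb2, a plasminogen activator inhibitor, reached 392 CPM in knockout 5 and 6 and 9.56 CPM in knockout 1 to 4, against 1.02 CPM in control 1 to 5 and 2.44 CPM in control 6, so that its smallest fold between sets was 3.85. Npnt, which encodes the integrin ligand nephronectin, rose from 9.77 ± 8.25 to 102.7 ± 12.1 CPM (SD, n = 6 each), with control 6 at 26.5 CPM and control 1 to 5 at 5.05 to 7.40 CPM. Prl2c4 has near-identical copies, so its own level is uncertain. The largest falls were in Derl3, Ednrb, Pdzd7, Igfbp3, Dlg2 and Avil, with log2 differences of -4.57 to -6.38. Control 6 was low in most of these, and the smallest fold between a control set and a knockout set was 1.17 for Derl3, 1.30 for Avil, 1.35 for Igfbp3, 1.56 for Dlg2 and 4.70 for Pdzd7. The growth factor binding protein Igfbp3 fell from 694 ± 308 to 23.7 ± 19.2 CPM, with control 6 at 66.1 CPM. The endothelin receptor Ednrb fell from 17.5 ± 7.17 to 0.283 ± 0.257 CPM and was at least 6.65-fold lower in each knockout set than in each control set.

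Across the 5219 genes, 3951 had both knockout sets beyond both control sets. That arrangement held for 43.5% of all tested genes. The average over the ways to pair the sets is 33.3%, and a single pairing can exceed it without a genotype effect, since genes are not independent. Of the 5219, 289 (66 higher, 223 lower) were separated by at least 2-fold in every contrast of sets. Over all tested genes, pairing by genotype put 290 at least 2-fold apart, and pairing knockout 1 to 4 with control 6 put 262. Of the 27 lists tested, 9 passed camera with its preset correlation (5 higher, 4 lower), 0 with an estimated correlation, and 14 passed fry, which asks whether a list's genes move one way without comparing them with other genes. With the counts of each set summed, so that 2 knockout sums met 2 control sums, the edgeR quasi-likelihood test called 0 genes at an adjusted p of 0.05 (1047 of 13132 at an unadjusted p under 0.05), limma-voom called 0 and DESeq2 198, and Tnfrsf1a stood at -0.59 (SE 0.31; edgeR unadjusted p = 0.104). Libraries simulated with the spread of these 4 sets and no changed gene gave 3958 calls over 12 libraries. Many of the 5219 observed calls can therefore arise from differences between the sets alone. The simulated count is a single draw in which genes varied independently, which real genes do not. The gap between 3958 and 5219 is thus no measure of a genotype effect. DESeq2 on the sums was not simulated, so its rate of false calls is not known here.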

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

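The tests of mislabelling and of summed library sets were chosen after the results they bear on had been seen.

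Dixon's ratio of gap to range flagged 39 of the 112 groups of 6 values examined, each time for control 6, where chance would give about 1 in 20. The 112 groups cover both genotypes, and control 6 belongs only to the control ones. The ratio takes the gap to the nearest value, so it misses 2 libraries that stand apart together, such as knockout 5 and 6. Control 6 also forms its own set by rank correlation, so its flags restate that split over genes that are not independent. Among genes that were lower in the knockout, its level in CPM was 54.9 for Tnfrsf1a, 1.78 for Derl3 (control 1 to 5 at 78.9 to 86.1), 3.18 for Ednrb, 1.65 for Pdzd7, 66.1 for Igfbp3 (800 to 854), 1.84 for Dlg2, 2.86 for Avil, 18.7 for Icam1, 74.2 for Col15a1, 6.10 for Col14a1, 46.3 for Mmp3, 147 for Mmp11, 7.82 for Ptgir, 5.47 for Oas1a, 12.3 for Psmb8, 75.3 for Sesn2, 37.3 for Mvd, 34.5 for Ndrg1, 18.1 for Egln3 and 40.6 for Lpl, each below control 1 to 5. It was above them at 251 for Sfrp1, 79.2 for Frzb, 336 for Tgfbr2 and 92.2 for C3, away from the knockouts. Among genes that were higher in the knockout, control 6 was above control 1 to 5 at 7.76 CPM for Prl2c4, 26.5 for Npnt, 18.7 for Cd24a, 62.1 for Chuk, 58.4 for Wnt5a, 4.26 for Id4, 1950 for Tagln, 3100 for Vim, 28.4 for Pdgfa, 1080 for Ptgs2 (202 to 210), 11.2 for Jag1, 28 for Hes1, 46.7 for Rrm2, 128 for Lmod1 and 8.65 for Ano1.

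A wrong label on control 6 was weighed on 1596 genes that part all 6 knockout libraries from control 1 to 5. These were also called, with a log2 difference over 1 either way, in an edgeR fit without control 6. On a scale from those controls (0) to the knockouts (1), the median position of control 6 was 0.524 (95% interval over genes, which are not independent, 0.498 to 0.55). Each knockout set was then held out, over genes chosen by separation and a log2 difference over 1 without the edgeR call. Knockout 5 and 6 gave 0.83 (1700 genes) and knockout 1 to 4 gave 0.398 (3124 genes). The genes differ, but held-out knockouts fell on both sides of control 6. This scale was therefore not shown to separate a knockout from a control culture, and the question stays open. Depth is argued against, since control 6 thinned to the lowest total of the other controls still correlated with them at 0.952 at the lowest, against 0.996 among themselves. A separate culture, animal or passage remains open and was not tested, because the labels give none per library.

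Knockout 5 and 6 stood apart from knockout 1 to 4. Counts taken by a few genes such as Rn45s are argued against, because 2450 genes differed over 2-fold between these sets after centring on the median gene, against 63 within knockout 1 to 4. Other cell types in the culture could not be settled. The highest median log2 difference among the 4 lists of non-mesenchymal markers with at least 3 tested genes was 0.66. It belonged to macrophage and leukocyte markers, whose most abundant member Lyz2 was at 33.6 against 27.8 CPM. The single tested mesothelial marker Wt1 was 3 higher on the log2 scale (5.85 against 0.588 CPM). Enteric glia and neuron markers were lower in knockout 5 and 6, with a median of -1.13 over 6 tested genes. This test looked for higher lists only, so it did not weigh other cells in knockout 1 to 4. Fibroblast subtype, smooth muscle and pericyte markers were not part of it. The labels name no difference between these sets, and no biological explanation was tested.

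The number of called genes was weighed against chance and against library sets counted as replicates. Of 100 splits of the 12 libraries into 6 and 6, drawn at random with the real one included, 1 gave as many calls as the 5219 of the real split, and the highest other count was 1845, for a split that put knockout 1 to 4 with control 6 and control 1, which follows the library sets. Such splits cannot exclude chance, because the split by genotype is the only one that keeps each of the 4 sets whole. Every other split divides very similar libraries between the groups, which widens the spread within groups whatever genotype does. Of the 3 ways to pair the 4 sets, 1 (by genotype) put as many as 290 genes at least 2-fold apart. The pairing of knockout 1 to 4 with control 6 put 262 apart, and 3 pairings are too few for a share under 0.05. With each set summed, 0 genes were called by edgeR (1047 at an unadjusted p under 0.05; DESeq2 198, limma-voom 0). That test also recovered 0% of simulated changes, so its 0 shows neither that the libraries of a set are near-copies of one culture nor that genotype had no effect, and both stay open.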

How the results depend on the processing

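The fits on summed sets, without knockout 5 and 6 (with or without control 6) and without Rn45s were chosen after the data had been seen. The test against a fold of 1.5 was run for counts only; no gene chosen by the naming rule reversed under the other alternatives. Apart from the summed sets, all 56 of those genes other than Tnfrsf1a kept their call under DESeq2 size factors, library totals alone, DESeq2, both filters, the fits without knockout 5 and 6 and the fit without Rn45s; 1 fell short in limma-voom (Ano1), 2 with the replicate block (Ano1 among them) and up to 3 with a library left out. Total calls ranged from 5142 to 5713 over the scalings, filters, DESeq2 and limma-voom and were 6488 without knockout 5 and 6, with 41.6% higher by library totals alone and 49.8% as reported. With sample quality weights limma-voom called 9095 genes (4452 higher, 4643 lower), against a fold of 1.5 there were 1173 (467 higher, 706 lower), and without knockout 5, knockout 6 and control 6 there were 8827 (4319 and 4508). With the sets summed, edgeR called 0 genes (0 higher, 0 lower), DESeq2 198 (64 and 134) and limma-voom 0 (0 and 0), and Tnfrsf1a was -0.591, -0.574 and -0.559 (adjusted p 0.629, 0.686 and 0.624). Of the 56 genes, 29 passed DESeq2 on the sums. That fit was not run on simulated counts, so its rate of false calls is not known here. The 56 genes were also chosen among calls over the same libraries. Fewer samples enter the summed fits. The fit without knockout 5, knockout 6 and control 6 holds 1 set per genotype, so only the spread within sets enters its p-values. The cause of the other shifts was not tested. Tnfrsf1a was otherwise -0.736 to -0.884, past the threshold in each fit that tested it. Lists past the threshold numbered 0 with an estimated correlation, 14 by fry and 15 on the sums, against 9 as reported; on the sums 0 passed with an estimated correlation and 0 by fry. In the fits without knockout 5 and 6, which keep 1 knockout set, no list passed camera with an estimated correlation both with and without control 6. With control 6 kept, NF-kB targets (adjusted p = 0.0433) and macrophage and leukocyte markers (0.0332) passed. These were at 0.133 and 0.0776 with control 6 out. Interferon-stimulated (0.0378) and glycolysis and hypoxia genes (0.0462) passed with control 6 out, but were at 0.345 and 0.0695 with it kept. All of these were lower in both fits. With each library left out in turn, calls ranged from 4432 to 6069, higher calls from 2148 to 3092, lower calls from 2270 to 2977, Tnfrsf1a from -0.835 to -0.736 and lists from 7 to 9. The replicate block gave 3974 calls (1867 higher, 2107 lower; 3927 shared with the 5219). Deviations of same-numbered libraries from their group means correlated at -0.364 to 0.184 and 0 of 6 knockout libraries correlated best with the control of its own number, so the numbers were not taken to pair samples. Of the Wnt ligands and R-spondins, 6 of 21 had counts high enough to test, and whether depth or lack of expression limits the others was not tested.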

Other observations

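The test of MHC class I and complement genes was chosen after their values had been seen.

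Many genes of MHC class I antigen presentation and of complement, which no list fixed in advance covers as a group, were lower in knockout libraries; Psmb8 and Tap1 also stand in the interferon list, and C3 and Cd55 in the trophocyte list. Of 15 tested MHC class I genes, 14 passed the edgeR test as lower and 0 as higher, with a median log2 difference of -1.40, and all 15 were lower in both knockout sets than in both control sets. H2-K1, a class I heavy chain, was at 54.0 against 214 CPM, and its copies are alike enough that reads may be split among family members. Of 13 complement genes, 8 fell, 1 rose and 4 did not pass, with a median of -1.49; C4b was at 1.81 against 20.6 CPM and factor B, Cfb, at 0.431 against 8.72 CPM. The hypothesis that both groups are lower in knockout cultures as groups was tested with camera on the 4 summed sets with an estimated correlation, which gave unadjusted p = 0.164 for MHC class I and 0.126 for complement, so it stays open.

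DNA carried along with the targeted allele could shift genes near Tnfrsf1a. Among the 100 tested genes nearest to it, 45 were called, within the 31 to 55 (median 43) that hold the middle 95% of 10000 windows of equal size (one-sided permutation p = 0.412 over randomly placed windows). That count argues against a broad excess of changed neighbours, and it does not speak to any single gene.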
